A study of Mus musculus with 24 samples.

How the data were processed

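The series holds 24 RNA sequencing libraries of mouse cerebellum, 6 for each of 4 genotype groups (Cre control, NDI1 control, cKO and cKO+NDI1), with 3 males and 3 females in each. Per the labels, whole cerebellum was frozen after dissection, total RNA was purified on columns with DNase treatment, and messenger RNA was selected by its polyA tail. Per the submitters' processing notes, bcl2fastq, Trimmomatic, STAR and HTSeq were used with the mouse build mm10; no versions are given. The deposited file holds raw read counts per gene and library: the values are whole numbers with no normalization by the authors. It has 43430 genes by Ensembl identifier, of which 42546 had a symbol in the reference annotation and 15557 had 0 counts in every library, and 0 per-library columns were left unused. A column of gene length in the deposited table is in bases; it is a property of the gene model and was used in a check of length trends alone.

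Groups, sexes and replicate numbers come from the labels. Replicate numbers run from M1 to M3 and F1 to F3; the labels give them no meaning, and they were not used to pair libraries. The sexes were checked on 4 Y-linked genes and Xist, and every library matched its label (Y genes at least 190 CPM in males and at most 2.18 in females). No pair of libraries within a group was a copy of another (smallest chi-square per degree of freedom 5.04 over 60 pairs). Labels give no batch, date or sequencing lane.

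Counts were normalised with TMM factors, genes with low counts were removed with filterByExpr by genotype group, and 15300 genes were tested. The test was edgeR's quasi-likelihood F test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3), in 1 model of all 24 libraries with genotype group and sex. P-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are CPM, counts scaled by TMM library sizes, and logs of CPM used a prior count of 2. The comparisons were cKO against Cre control, cKO+NDI1 against cKO, against NDI1 control and against Cre control, NDI1 control against Cre control, the interaction of knockout and NDI1, male against female, and the knockout's effect in males minus that in females.

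For gene groups, 38 lists were tested with camera at a preset correlation of 0.01, adjusted over the 38 lists within each comparison, with camera at an estimated correlation and fry beside it. The share of the knockout's effect kept with NDI1 was a slope through 0 over genes called in cKO against Cre control, with its error from leaving out each library in turn. The signed mean of these genes was compared between cKO+NDI1 and NDI1 control by an exact two-sided permutation of genotype within each sex. For gene overlaps between comparisons that share a group, chance was taken from independent lists of the same size, and the overlap was also counted with the shared libraries divided between the comparisons.

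Genes named in the text follow a rule. Fixed genes (among them Gfap, Aif1, Asns, Gdf15, Fgf21, Trib3, Atf3, Ldha, Pcp2, Calb1, Gabra6, Mbp, Nnt, Serpina3n and C4b) are measured in every comparison where they could be tested. To these are added, among genes that passed with a mean log2 CPM of at least 1, the 8 highest and 8 lowest log2 fold changes per main comparison (4 and 4 for NDI1 control against Cre control and for the difference between sexes, and the 3 and 3 smallest p for male against female). For a list that passed camera or had at least 3 called members, up to 4 called members with the smallest p are added. Predicted genes and pseudogenes were passed over. Named outside the rule, after their values were seen, were Fkbp5 and Wdfy1, and Pecam1, Slc1a3 and Tubb2b in comparisons that did not select them. The groups, lists, tests, named-gene rule and most alternatives were choices made before the data were examined.

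The pipeline was tested on simulated counts made from these libraries with known changes added. In cKO against Cre control it recovered 21.2% of genes changed by a log2 of 0.3, 67.5% at 0.6 and 89.7% at 1. At 0.6 it recovered 62.9% in cKO+NDI1 against cKO, 78.0% in cKO+NDI1 against NDI1 control, 67.3% in cKO+NDI1 against Cre control, 58.8% in NDI1 control against Cre control, 30.3% in the interaction, 88.3% in male against female and 3.45% in the difference between sexes. A kept slope of 0.5 was fitted as 0.451, and a list raised by 0.3 was called with 0 of the other lists. Simulated genes were drawn independently, so this check says nothing about false list calls where genes are correlated. For the same reason, recovery of single genes in the real libraries may differ.

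Depth ranged from 7584374 to 19785264 counts per library. It was lower in cKO, so counts were also thinned to the smallest total. Other alternatives were RLE size factors and library size alone, DESeq2 1.42.0 and limma-voom, no filter (at least 1 count in all) and a stricter one (CPM of at least 1 in 6 libraries), a fold threshold of 0.5 on the log2 scale, no sex term, the replicate number as a block, each sex alone, the compared groups alone, and leaving out each library. Added after seeing the data were offsets corrected for gene length and GC content (5 spline degrees of freedom; GC known for 99.4% of tested genes), 1 surrogate variable from svaseq (sva 3.50.0), and ratios of mean signed changes between sexes. No library was left out of the main results.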

Results

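Messenger RNA was sequenced from the whole cerebellum of 24 mice of about 7 weeks of age. The mice formed 4 genotype groups of 6, each with 3 males and 3 females, and each library came from 1 mouse. The Cre control and the NDI1 control are the controls. The cKO mice carry a conditional knockout that impairs complex I, the first enzyme of the mitochondrial respiratory chain, in the brain. The cKO+NDI1 mice carry the knockout together with NDI1, a yeast NADH dehydrogenase that oxidises NADH to NAD+ without pumping protons. The study's title asks about NAD+ regeneration, lifespan and ataxia; the comparisons therefore ask what the knockout changed in cerebellar RNA, and how much of that change remained when NDI1 was present. Library totals ranged from 7584374 to 19785264 counts and were lowest on average in cKO. Of the genes in the table, 15300 had enough counts to be tested.

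The labels do not name the gene knocked out, and no check of the knockout is given here. The noncoding RNA of the Rosa26 locus, Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333), where NDI1 is known to be inserted in this line, separated the groups with NDI1 from those without. It stood at 35.7 ± 7.53 CPM (counts scaled by library size; mean ± SD, n = 6 per group here and below) in the Cre control and 34.8 ± 8.14 in cKO, and at 7.01 ± 0.879 in the NDI1 control and 7.04 ± 1.35 in cKO+NDI1. No library with NDI1 overlapped one without.

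The first comparison, cKO against Cre control, asks what the knockout changed. Endothelial genes were higher in cKO, and most changes were moderate. The lists of Bergmann glia and astrocytes and of glycolysis were lower by camera, with 1 of 19 and 2 of 23 genes called, but not with an estimated correlation (adjusted p = 0.297 for each). Pecam1, an adhesion molecule of endothelial cells (chromosome 11, 106654217 to 106750628), stood at 46.9 ± 5.32 CPM in cKO and 27.8 ± 2.07 in the Cre control, a rise of 1.69-fold (log2 0.76 ± 0.09, SE for log2 values here and below; adjusted p = 0.000151), and every cKO library lay above every Cre control library. Fabp7, a fatty acid binding protein of Bergmann glia and other radial glia (chromosome 10, 57784881 to 57788450), fell from 144 ± 19.4 to 73.1 ± 19.9 CPM (log2 -0.97 ± 0.18, adjusted p = 0.00211). In all, 745 of 15300 genes passed the test, 468 higher and 277 lower, with a median absolute log2 fold change of 0.39; 257 changed by a log2 of at least 0.5. The split of higher and lower was 543 and 221 with library size alone, 499 and 431 with offsets corrected for gene length and GC content, and 1505 and 1680 with 1 surrogate variable.

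Among the 17 tested endothelial genes, 15 had positive log2 fold changes and the median was 0.25. Of these, 2 rose over all genes tested, Pecam1 and Ctla2a (12.8 ± 1.53 to 30.1 ± 11.3 CPM), and 7 rose when adjusted over the list alone. The list as a group was higher by camera (adjusted p = 4.3e-06) and remained so with an estimated correlation (adjusted p = 0.000626). Edn1, which encodes endothelin and is secreted by endothelial cells, rose by a log2 of 1.34 ± 0.21, from 3.26 ± 0.398 to 8.48 ± 3.55 CPM. Of 11 genes of pericytes and smooth muscle, 4 rose over all genes tested and 5 when adjusted over the list alone. Acta2, the actin of smooth muscle, rose from 17.4 ± 3.40 to 31.0 ± 2.87 CPM (log2 0.84 ± 0.15), while the calls of Rgs5, Cnn1 and Myh11 each ended with some single libraries left out. This list passed camera (adjusted p = 0.00101) but not with an estimated correlation (adjusted p = 0.149). The lists for other cells that surround the brain moved less. The meningeal fibroblast genes had a median of 0.03 and the choroid plexus genes one of 0.15, and neither list passed camera (adjusted p = 0.563 and 0.306).

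Of 19 genes of astrocytes and Bergmann glia, 17 had negative log2 fold changes (median -0.10). Slc1a3, the glutamate transporter that is abundant in Bergmann glia, fell from 2112 ± 93.2 to 1743 ± 85.7 CPM (log2 -0.28 ± 0.05, adjusted p = 0.00262); it was the 1 gene of the list called over all genes tested, against 5 adjusted over the list alone. Camera gave an adjusted p of 0.00172 for the list (adjusted p = 0.297 with an estimated correlation). Tnc, an extracellular matrix protein of astrocytes, fell by 0.88 ± 0.21 on the log2 scale. Reactive astrocyte genes moved the other way. Of 29 tested, 25 had positive values, 3 rose and 1 fell over all genes tested, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000603; adjusted p = 0.297 with an estimated correlation). Timp1, an inhibitor of metalloproteinases, rose by 1.28 ± 0.26 and Cxcl10, a chemokine induced by interferon, by 2.21 ± 0.50. Both had low counts. Timp1 stood at 0.371 to 0.788 CPM in the Cre control and 0.775 to 2.16 in cKO. Cxcl10, which is also in the list of interferon-stimulated genes, stood at 0.131 to 1.19 and 0.683 to 4.10. Gfap did not pass the test (log2 0.25 ± 0.07, adjusted p = 0.0536), but passed in 6 of 14 other settings.

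Of 29 interferon-stimulated genes, 26 had positive values, 3 rose over all genes tested (Irf7, log2 1.11 ± 0.26; Stat2, 0.37 ± 0.09; and Cxcl10), and 7 adjusted over the list alone. The list passed camera (adjusted p = 2.7e-05) but not with an estimated correlation (adjusted p = 0.401). The complement gene C4b rose by 0.81 ± 0.18 (adjusted p = 0.0101). Called genes of antigen presentation went both ways. H2-K1 (log2 0.47, adjusted p = 0.0229) and Tapbp (0.23, adjusted p = 0.0424) rose. Cd74 (-0.72, adjusted p = 0.0336) and H2-Aa (-0.76, adjusted p = 0.0339) fell. In this order, their calls ended in 4, 18, 7 and 8 of 24 fits that left out 1 library. Homeostatic microglia genes did not pass (median 0.06, adjusted p = 0.570), nor did those of disease-associated microglia (median 0.01, adjusted p = 0.396), and Aif1, a microglial marker, differed by -0.09 ± 0.18.

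Glycolysis and lactate genes had negative values in 19 of 23 (median -0.10). Eno1, the enolase found in most tissues, fell from 395 ± 29.9 to 311 ± 27.0 CPM (log2 -0.34 ± 0.06). Hk2, a hexokinase, also fell (log2 -0.67 ± 0.17), a call that ended without Cre control replicate M3 (adjusted p = 0.0617). These were the 2 called over all genes tested, against 8 lower and 1 higher adjusted over the list alone; camera gave an adjusted p of 0.00172, but the adjusted p = 0.297 with an estimated correlation. All 8 tested respiratory chain genes of the mitochondrial genome had positive values (median 0.37), and mt-Co1, a subunit of cytochrome oxidase, rose by 0.88 ± 0.17. That list passed camera (adjusted p = 0.00172), but the adjusted p = 0.401 with an estimated correlation. Mitochondrial RNA in all took 1.89% ± 0.241 of counts in the Cre control and 2.78% ± 0.499 in cKO. Nuclear subunits of complex I had small negative values in 34 of 37 (median -0.09, 1 lower; camera adjusted p = 0.00219; adjusted p = 0.632 with an estimated correlation). Targets of the integrated stress response, the ATF4 program that rises in many mitochondrial diseases, were not higher: 34 of 38 had negative values (median -0.19), 0 passed edgeR's test in either adjustment, and Asns differed by -0.34 ± 0.14 (adjusted p = 0.162). The list was lower by camera (adjusted p = 8.4e-05; adjusted p = 0.401 with an estimated correlation). Gdf15 and Fgf21 had too few counts to be tested.

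Markers of the main cerebellar neurons did not pass the test. Pcp2 of Purkinje cells stood at 661 ± 133 CPM in the Cre control and 686 ± 90.8 in cKO, Calb1 at 1671 ± 77.1 and 1641 ± 120, and Gabra6 of granule neurons at 1032 ± 125 and 965 ± 65.1. Among receptors, the log2 level of Grin2c rose by 0.28 ± 0.06 and Gria4 fell by 0.23 ± 0.05. Other genes with large changes were Th (log2 1.25 ± 0.23), the rate-limiting enzyme of catecholamine synthesis, Gpx3 (1.34 ± 0.26), a secreted glutathione peroxidase, and Bcl6b (1.35 ± 0.29), all higher. Traf1 (-0.82 ± 0.13), Hist1h2be (-0.93 ± 0.15), Sost (-1.17 ± 0.26), Abca8a (-0.86 ± 0.18) and Pkd2l1 (-0.81 ± 0.17) were lower. Some genes of the immediate early and stress responses rested in part on cKO replicate F1. The log2 fold change of Maff was 2.03 ± 0.48 and without this library 1.12, that of Cdkn1a 0.81 ± 0.20 and 0.46, and that of Fosb 2.96 ± 0.85 and 0.80, where Fosb no longer passed (adjusted p = 0.538); the Fosb call was lost in 14 of 24 fits that left out 1 library and in 7 of 14 other settings. Males alone gave 38 genes and females alone 364, and a fit to these groups alone gave 263.

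The second comparison, cKO+NDI1 against cKO, asks what NDI1 changed in knockout mice. Some genes that the knockout had lowered were higher with NDI1. Of 22 myelin genes 5 were lower, and the list was lower by camera but not with an estimated correlation (adjusted p = 0.145). Tubb2b, a beta-tubulin of growing neurites (chromosome 13, 34127008 to 34130354), rose from 94.4 ± 10.1 CPM in cKO to 140 ± 12.2 in cKO+NDI1 (log2 0.57 ± 0.09, adjusted p = 0.00547), with every cKO+NDI1 library above every cKO library; in the Cre and NDI1 controls its means were 145 and 160. Mobp, a myelin protein, fell from 1781 ± 337 to 1159 ± 115 CPM (log2 -0.62 ± 0.10, adjusted p = 0.00728), against 1528 ± 114 in the Cre control and 1286 ± 138 in the NDI1 control.

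Of 15300 genes, 32 passed, 13 higher and 19 lower; the majority turned with DESeq2 (56 and 50), with 1 surrogate variable (252 and 191) and without cKO+NDI1 replicate F1 (18 and 12) or cKO replicate F3 (18 and 13). The largest change was that of Gt(ROSA)26Sor (log2 -2.30 ± 0.16). Of 22 tested genes of oligodendrocytes and myelin, 21 had negative values (median -0.30), 5 fell over all genes tested and 14 when adjusted over the list alone. Mal fell by 0.67 ± 0.11 on the log2 scale and Tspan2 fell by 0.52 ± 0.08; Cldn11 (-0.56 ± 0.10) and Mbp (-0.49 ± 0.09) also passed, but not with some single cKO+NDI1 libraries left out. Camera called the list (adjusted p = 9.4e-22), but the adjusted p = 0.145 with an estimated correlation. Slc13a3, a transporter of dicarboxylates, rose by 0.44 ± 0.08. Traf1 rose by 0.71 ± 0.13 and Gpx3 fell by 1.27 ± 0.26, to 5.98 ± 2.20 CPM against 5.57 ± 1.42 in the Cre control; these calls ended in 4 and 11 of 24 fits that left out 1 library. Glycolysis genes had positive values in 19 of 23 (median 0.10; 0 called over all genes tested, 1 adjusted over the list alone; camera adjusted p = 0.000181; adjusted p = 0.238 with an estimated correlation). All 37 nuclear complex I subunits had positive values (median 0.13), with 0 called in either adjustment; camera gave an adjusted p of 0.000181, but the adjusted p = 0.668 with an estimated correlation.

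Of the 32 genes, 19 had also passed in cKO against Cre control, all in the opposite direction and 0 in the same one. Both comparisons share the cKO libraries. Independent lists of this size would share 0.817 by chance in the opposite direction, a number that leaves out the shared libraries. With the cKO libraries divided between the comparisons, a first division gave 576 and 46 genes with 2 shared in the opposite direction and 6 in the same one, and a second gave 245 and 52 with 8 in the opposite direction and 0 in the same. The count of 32 fell to 10 without cKO+NDI1 replicate M2 and to 11 without F3, and a fit to the cKO and cKO+NDI1 groups alone gave 13.

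The third comparison, cKO+NDI1 against NDI1 control, asks what the knockout changed where NDI1 was present in both groups. No single gene passed, and genes of blood vessels had mostly positive values. Among the 17 endothelial genes 11 were positive (median 0.14), with 0 called over all genes tested and 2 adjusted over the list alone (camera adjusted p = 0.00155; adjusted p = 0.0645 with an estimated correlation). Pecam1 stood at 38.1 ± 3.59 CPM in cKO+NDI1 and 28.3 in the NDI1 control (log2 0.43 ± 0.09, adjusted p = 0.154), and Slc1a3 at 1835 ± 103 and 2154 ± 112. Of 15300 genes, 0 passed edgeR's test, with 686 at an unadjusted p under 0.05; limma-voom gave 0, DESeq2 23 and edgeR with 1 surrogate variable 53. In simulated data of the same depth and per-gene spread the same test recovered 46 of 59 genes changed by a log2 of 0.6 and 12 of 63 changed by 0.3. Those simulated genes lack the correlation between genes of the real libraries, so recovery there may differ.

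Some lists passed camera here. Interferon-stimulated genes were higher (26 of 29 positive, median 0.24, 0 called over all genes tested, 5 adjusted over the list alone; adjusted p = 2.8e-10), as were homeostatic microglia genes (20 of 20 positive, median 0.18, 0 in either adjustment; adjusted p = 5.0e-09), and cholesterol synthesis genes were lower (22 of 23 negative, median -0.14, 0 in either adjustment; adjusted p = 4.9e-08). None of the 3 held: their adjusted p values were 0.167, 0.0881 and 0.147 with an estimated correlation.

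Over the 745 genes called for the knockout without NDI1, the changes with NDI1 had a slope through 0 of 0.37 (jackknife SE 0.10) against those without, and 90.3% had the same direction. These genes were picked for large values in the first comparison, which lowers the slope. Genes picked in one sex were therefore measured in the other: slopes were 0.387 for 38 genes picked in males (73.7% in the same direction) and 0.583 for 363 picked in females (70.2%). On the same genes, the mean signed change of cKO+NDI1 against cKO was -0.20 for those picked in males and measured in females, and 0.05 for those picked in females and measured in males. For the latter, cKO+NDI1 against Cre control was 1.24 times cKO against Cre control, and for the former 0.581 times. The mean log2 level of the 745 genes, signed by direction and set to 0 in the Cre control, was 0.481 ± 0.0648 in cKO, 0.290 ± 0.0592 in cKO+NDI1 and 0.133 ± 0.0383 in the NDI1 control (SD, n = 6 each). The difference of 0.156 between cKO+NDI1 and NDI1 control had p = 0.005 by an exact two-sided permutation test within sex, the smallest that its 400 relabelings can give. All cKO+NDI1 libraries lay above all NDI1 control libraries. Across all 15300 genes, which are not independent replicates, the knockout's changes with and without NDI1 correlated at r = 0.413 (Spearman rho 0.393).

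**Figure D1:**
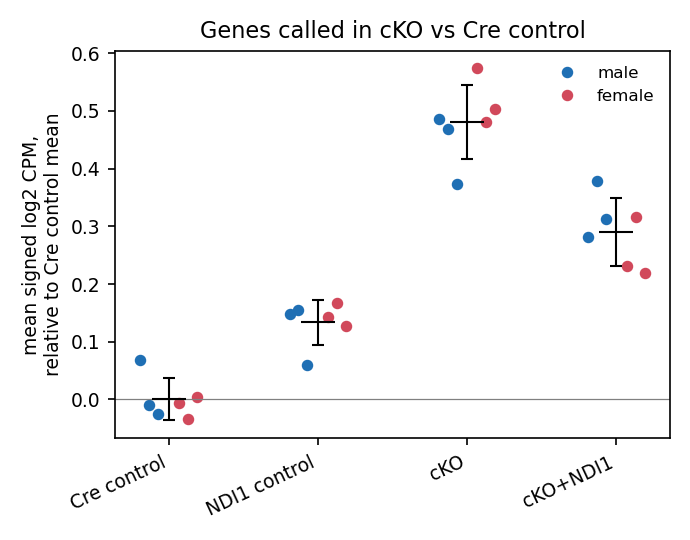
Mean signed log2 CPM of the 745 genes called in cKO against Cre control, relative to the Cre control mean, for each library (blue: male, red: female), with the mean and SD of each group of 6. The genes were picked for the gap between Cre control and cKO; the cKO+NDI1 mean (0.290) lies between those of the NDI1 control (0.133) and cKO (0.481), and cKO+NDI1 replicate M2 (0.378) lies above cKO replicate M3 (0.373).

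Whether the knockout's effect differed with NDI1 was tested directly as an interaction. Of 15300 genes, 0 passed edgeR's test, with 792 at an unadjusted p under 0.05; limma-voom gave 0 and DESeq2 12. Pecam1 differed by -0.33 ± 0.13 (adjusted p = 0.852) and Tubb2b by 0.42 ± 0.12 (adjusted p = 0.655). The endothelial list was the one list that passed with an estimated correlation: the knockout's rise was smaller with NDI1 (median -0.24, 14 of 17 negative, 0 called in either adjustment; camera adjusted p = 0.00251; adjusted p = 0.0369 with an estimated correlation). Power was low here, as 30.3% of genes with a simulated difference of 0.6 were recovered. Without Cre control replicate M1 the count was 4.

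The comparison of cKO+NDI1 with Cre control asks how far the knockout mice with NDI1 stood from mice with neither. Endothelial genes were higher. The lists of myelin and of targets of the integrated stress response were lower by camera, with 4 of 22 and 4 of 38 genes called, but not with an estimated correlation (adjusted p = 0.144 and 0.0851). Pecam1 rose by 0.46 ± 0.09 (adjusted p = 0.0160; 0.0511 without Cre control replicate M2) and Acta2 by 0.73 ± 0.15 (adjusted p = 0.0181; 0.0521 without Cre control replicate M3). Gjc3, a connexin of myelinating cells, fell from 130 ± 7.23 to 105 ± 3.81 CPM (log2 -0.32 ± 0.06, adjusted p = 0.00848). In all, 191 of 15300 genes passed, 129 higher and 62 lower. This split was 194 and 31 with library size alone, 93 and 87 with offsets corrected for gene length and GC content, and 739 and 891 with 1 surrogate variable. The count ranged from 26 without cKO+NDI1 replicate M2 to 279 without Cre control replicate M1; females alone gave 2.

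The endothelial list (17 tested, 2 called over all genes tested, 5 adjusted over the list alone) passed camera (adjusted p = 2.4e-05) and with an estimated correlation (adjusted p = 0.00239), and so did pericytes and smooth muscle (11 tested, 1 and 5; adjusted p = 6.0e-05, and 0.0487 with an estimated correlation). Of 22 myelin genes 4 fell, and 11 adjusted over the list alone (median -0.29; camera adjusted p = 2.6e-13; adjusted p = 0.144 with an estimated correlation). Of 38 stress response targets 4 fell, and 21 adjusted over the list alone (median -0.25; camera adjusted p = 2.1e-16; adjusted p = 0.0851 with an estimated correlation). The genes that fell were Asns, which makes asparagine (log2 -0.55 ± 0.14), the mitochondrial folate enzyme Mthfd2 (-0.60 ± 0.15) and the tRNA synthetases Nars (-0.34 ± 0.08) and Gars (-0.36 ± 0.09); each lost its call in at least 15 of 24 fits that left out 1 library. With cKO against Cre control, 123 genes were shared in the same direction and 0 in the opposite one. Both share the Cre control libraries; independent lists would share 5.07, and with the Cre control libraries divided, 9 were shared between 119 and 17 genes in one division and 0 between 278 and 1 in the other.

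NDI1 control against Cre control asks what NDI1 changed in mice without the knockout. Gt(ROSA)26Sor was lower (log2 -2.35 ± 0.16, adjusted p = 3.7e-09) and was the 1 gene of 15300 that passed, with 1408 at an unadjusted p under 0.05; limma-voom gave 3 and DESeq2 77. The count was 31 without Cre control replicate M1 and 37 without NDI1 control replicate M3. Of 38 stress response targets, 36 had negative values (median -0.24), 0 passed over all genes tested and 19 fell when adjusted over the list alone (camera adjusted p = 3.6e-21; adjusted p = 0.103 with an estimated correlation). Asns stood at 89.9 ± 21.9 CPM against 127 ± 12.5 (log2 -0.51 ± 0.14, adjusted p = 0.212). Myelin genes had a median of -0.18, with 20 of 22 negative, 0 called over all genes tested and 3 adjusted over the list alone (camera adjusted p = 4.1e-06; adjusted p = 0.685 with an estimated correlation).

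**Figure D2:**
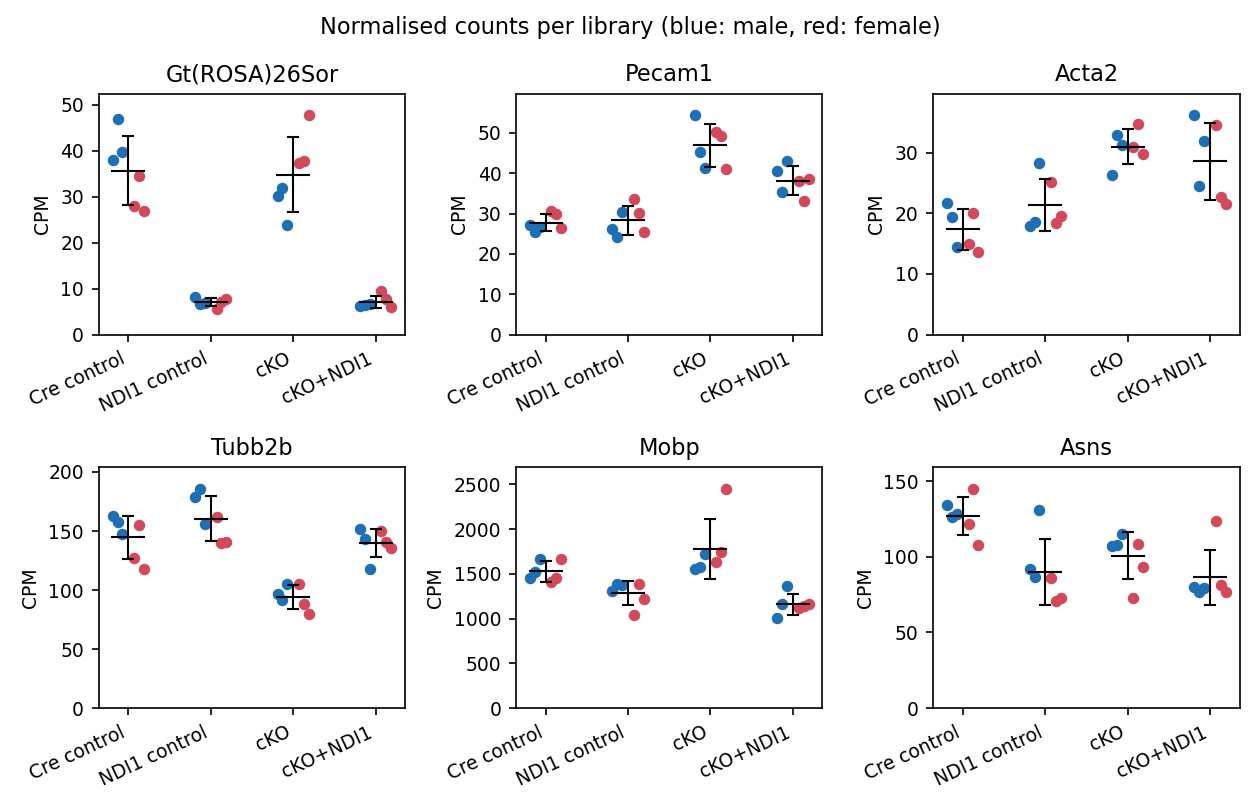
CPM of 6 genes in each library (blue: male, red: female), with the mean and SD of each group of 6. Gt(ROSA)26Sor is near 7 CPM in both groups with NDI1, Pecam1 is highest in cKO (46.9), Tubb2b is lowest in cKO (94.4), and Asns is highest in the Cre control (127).

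**Figure D3:**
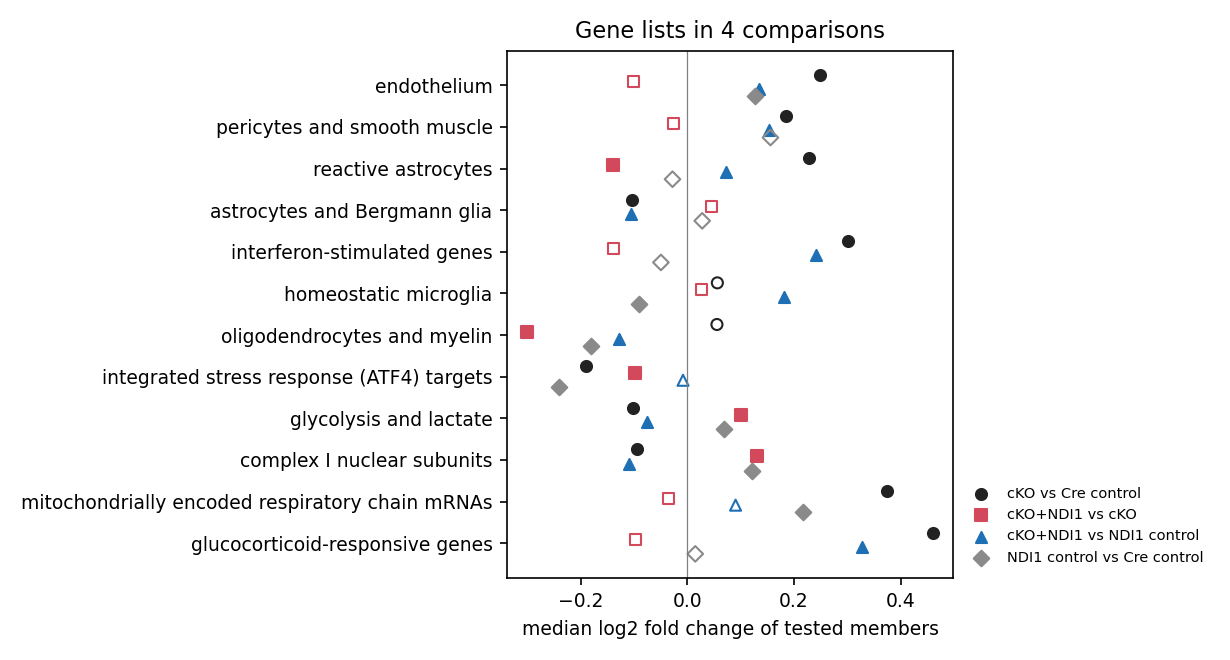
Median log2 fold change of the tested members of 12 lists in 4 comparisons. Filled symbols have a camera adjusted p under the threshold of 0.05 and open ones do not; the endothelial list has its highest median in cKO against Cre control (0.25) and the myelin list its lowest in cKO+NDI1 against cKO (-0.30).

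Male against female mice, with genotype accounted for, asks what sex changed. Of 15300 genes, 13 passed, 6 higher and 7 lower in males. The Y-linked genes Uty, Kdm5d and Eif2s3y were higher, and Xist, which silences 1 X chromosome in females, was lower (log2 -12.02 ± 0.30). Kdm6a (-0.63 ± 0.05) and Eif2s3x (-0.50 ± 0.05), X-linked genes that escape this silencing, were lower in males. The count was 33 without cKO replicate M3, 22 without cKO replicate F2 and 3977 in a fit to the 2 control groups alone. Males and females of these control groups also mostly lay apart on the first principal component of the samples. Whether the count of 3977 came from sex or from that component was not tested. The test of whether the knockout's effect, cKO against Cre control, differed between males and females gave 0 genes by edgeR, with 3147 at an unadjusted p under 0.05, 0 by limma-voom and 11 by DESeq2. In simulated data it recovered 38.6% of genes that differed by a log2 of 1 and 3.45% of those that differed by 0.6.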

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

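Tests of the Cre control standing apart, of surface tissue, of blood and of a lower share of neurons, the offsets corrected for gene length and GC content, and the surrogate variable, were chosen only after the data had been seen. Values are given first, and 3 patterns are weighed after them.

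Some libraries lay far from the other 5 of their group. Chance alone marks about 1 in 20 groups this way, and 13 of the 304 groups tested were marked, so single cases need no cause. The mean signed level of the 745 genes of cKO against Cre control was 0.0689 in Cre control replicate M1. In cKO, Hk2 stood at 18.5 CPM in M3, Slc1a3 at 1909 in M2, Cdkn1a at 106 in F1, Tapbp at 40.1 in F3 and Mobp at 2450 in F3. In the Cre control, Cnn1 stood at 0.239 CPM in F3, Edn1 at 2.45 in F3 and Mbp at 5251 in F1. In cKO+NDI1, Sost stood at 4.17 CPM in F1, Asns at 124 in F1, Trib3 at 5.11 in F1 and Abca8a at 6.05 in M3.

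Gene lists whose knockout effect differed with NDI1, by camera on the interaction, had these median differences: -0.28 for respiratory chain mRNAs of the mitochondrial genome, 0.18 for targets of the integrated stress response, 0.13 for homeostatic microglia, -0.21 for myelin and -0.24 for endothelium. With an estimated correlation the endothelial list passed (adjusted p = 0.0369) and the others did not. Lists whose knockout effect differed between males and females had these median differences (males minus females): -0.52 for nuclear subunits of complex I, -0.29 for its assembly factors, -0.51 for subunits of complexes II to V, 0.50 for interferon-stimulated genes, 0.15 for granule neurons, -0.27 for myelin, 0.87 for choroid plexus, 0.39 for voltage-gated channels and 0.23 for glutamate and GABA receptors. None of these 9 lists passed with an estimated correlation. In the Cre control, males stood at -27.3, -11.6 and 4.99 on the first principal component and females at 25.2, -6.91 and 38.9. In cKO, males stood at -2.85, 10.1 and 17.6 and females at 21.3, -4.34 and -10.5. With 1 surrogate variable, which correlates with that component, genes at an unadjusted p under 0.05 for males minus females fell from 3147 to 1512. A difference by sex in these lists therefore cannot be told apart from that structure of the samples.

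The first pattern is that the knockout called 745 genes without NDI1 and 0 with it (3185 and 53 with 1 surrogate variable). The tables argue against the fitted trend in gene length and GC content, since 0 genes were called in cKO+NDI1 against NDI1 control with corrected offsets. That trend held a median of 8.91% of the variance of a library's deviations, and at most 19.7%. Other differences between libraries are not covered by this correction, here and in the next patterns. The tables also argue against a single library standing apart in these groups, since leaving one out gave at most 2. A Cre control group that stands apart from the other 3 groups cannot be told apart from an effect of the knockout, because the 2 directions of the test disagreed: over genes picked in one sex and measured in the other, the mean signed change of NDI1 control against Cre control was 0.624 times that of cKO in one direction and 0.262 times in the other. An effect of NDI1 on the knockout's changes, which the design names, also stays open: the interaction called 0 genes with low power and 55 with 1 surrogate variable, and the endothelial list passed it with an estimated correlation (adjusted p = 0.0369).

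The second pattern is that endothelial and mural genes were higher by camera in cKO than in the Cre control, the mural list not with an estimated correlation (adjusted p = 0.149, 4 of 11 genes called). The tables argue against a lower share of neurons, which would raise every other cell type alike: the lowest median among oligodendrocyte, precursor, astrocyte and homeostatic microglia lists was -0.11, that of the precursors, against 0.25 for endothelium. They argue against more blood, since all 10 tested blood genes had negative values. The median of -0.39 was just beyond the median standard error of the members (0.373) and beyond their SD (0.326). That list did not pass with an estimated correlation. The tables also argue against a trend in gene length and GC content, since the endothelial median was 0.27 with corrected offsets. Tissue of the brain surface or the ventricle lining cannot be told apart from a change in the vessels, because the lists disagreed: the meningeal median of 0.03 was lower than this explanation needs, with members that went both ways, and the choroid plexus median of 0.15 was too high to exclude it. More vessel tissue per sample, or more RNA of these genes per vessel cell, stays open as an untested effect of the knockout.

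The third pattern is that myelin genes were lower by camera in cKO+NDI1 than in cKO, with 5 of 22 genes called, but not with an estimated correlation (adjusted p = 0.145). The tables argue against a trend in gene length and GC content, with a median of -0.27 with corrected offsets, and against a single library, with a median of -0.19 in the fit closest to 0 that left out 1 library. Less brainstem tissue in the cKO+NDI1 samples cannot be told apart from a change in myelin: the median of 5 brainstem neuron genes was 0.27, within the median standard error of its members (0.301), and these genes had few counts. The rule set beforehand counted any median above 0 against this explanation, and the standard error was not part of it. The share of white matter in each sample was not tested. An effect of NDI1 on oligodendrocytes, which the design names, stays open.

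Whether chance can be excluded was asked with 100 splits of the libraries per count, the real one included. No other split reached the 32 genes of cKO+NDI1 against cKO (1 split as large, highest other 8). The same held for the 13 of male against female (1 split, highest other 0). Chance is unlikely for these counts. For the other counts above 0, few splits were as large, but some called far more genes. These were the 745 of cKO against Cre control (3 splits, highest other 4261) and the 191 of cKO+NDI1 against Cre control (2 splits, highest other 2794). The third was the 1 of NDI1 control against Cre control (2 splits, highest other 4292). Chance is less likely there but is not excluded for the counts. The 1 gene of the third is Gt(ROSA)26Sor, and a count over splits does not test the call of that gene itself. It stood at 26.9 to 46.9 CPM in the Cre control and 5.66 to 8.18 in the NDI1 control. For counts of 0 this test decides nothing, since every one of 100 splits is as large by construction: cKO+NDI1 against NDI1 control (highest other 3519), the interaction (highest other 0) and the knockout's effect in males minus females (highest other 1). Splits that call several times the real count point to a structure of the samples other than the groups. In the 4 comparisons concerned, the split with the highest count was the one with the largest gap in the first principal component, which held 32.3% of the variance.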

How the results depend on the processing

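Offsets corrected for gene length and GC content, the surrogate variable and the ratios of mean signed changes were chosen after the data had been seen. Counts of called genes were within 1.5 times of the main one in 231 of the settings tried, higher in 25 and lower in 35, and 12 moved from 0. For named genes, no call turned its direction; 6487 results stayed on their side of the threshold, 667 calls were lost and 23 gained. For single lists, 762 results were unchanged in this sense and 221 calls were lost. RLE size factors, library size alone and the stricter filter left every count within 1.5 times. Of 85 calls of named genes, 41 held with each library left out and 9 held under all other settings.

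The lower counts of this paragraph come with fewer libraries or counts, more genes tested or a fold threshold, and for the higher ones the cause was not tested. Males alone gave 38 genes for cKO against Cre control, 2 for cKO+NDI1 against cKO, 1 for cKO+NDI1 against NDI1 control and 14 for cKO+NDI1 against Cre control; females alone gave 364, 2, 0 and 2, and 2 for NDI1 control against Cre control. The compared groups alone gave 263 for cKO against Cre control and 13 for cKO+NDI1 against cKO. Counts thinned to the smallest library gave 494, 19, 92 for cKO+NDI1 against Cre control and 4 for NDI1 control against Cre control, so depth limits how many moderate changes can be called. A log2 threshold of 0.5 gave 257, 17 and 80 in the 3 comparisons with most calls, and no filter, which tests more genes, gave 425, 21 and 87, with 2 for cKO+NDI1 against NDI1 control and 5 for males minus females.

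Leaving out each library in turn gave 504 to 914 genes for cKO against Cre control, 10 to 42 for cKO+NDI1 against cKO, 0 to 3 for cKO+NDI1 against NDI1 control, 26 to 279 for cKO+NDI1 against Cre control, 1 to 37 for NDI1 control against Cre control, 0 to 4 for the interaction, 10 to 33 for male against female, 0 for males minus females, and a kept slope of 0.298 to 0.389.

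For the following the cause was not tested. DESeq2 gave 1123 genes for cKO against Cre control, 106 for cKO+NDI1 against cKO, 23 for cKO+NDI1 against NDI1 control, 503 for cKO+NDI1 against Cre control, 77 for NDI1 control against Cre control, 12 for the interaction, 32 for male against female and 11 for males minus females. With 1 surrogate variable the first 7 of these were 3185, 443, 53, 1630, 292, 55 and 23; that variable correlates with the first principal component. NDI1 control against Cre control had 3 genes by limma-voom, 2 without the sex term and 5 with corrected offsets. Male against female gave 3977 genes in the 2 control groups alone. The kept slope of 0.369 was 0.583 for genes picked in females and measured in males (0.615 as a ratio of mean signed changes). For genes picked in males and measured in females it was 0.387 (0.320 as such a ratio). Against the Cre control it was 0.607, where both sets of changes share the Cre control libraries. Of 99 list results called among 304, 4 passed with an estimated correlation and 18 by fry. The direction of 5 lists turned with the surrogate variable (adjusted p): nuclear complex I subunits in NDI1 control against Cre control (0.671) and in male against female (0.272), complexes II to V (0.172) and voltage-gated channels (0.238) in male against female, and voltage-gated channels in males minus females (0.0507).

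The replicate numbers share only a number between groups. Deviations from the group means correlated at -0.40 to 0.51 between libraries of the same number. The mean correlation ran from -0.10 for F1 to 0.34 for M3. Of 24 libraries, 11 correlated best with their own number, out of 3 numbers of the same sex, so a share would match by chance. This is at most a weak hint from the data, and the design gives none. With the number as a replicate block, the counts were 754 for cKO against Cre control, 20 for cKO+NDI1 against cKO, 0 for cKO+NDI1 against NDI1 control, 200 for cKO+NDI1 against Cre control, 2 for NDI1 control against Cre control, 0 for the interaction and 0 for males minus females, the kept slope was 0.343, and 89 list results were called. The block, the single sexes and the fit without sex give no value for male against female, and the compared groups alone give none for the interaction.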

Other observations

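In cKO against Cre control, of 16 genes induced by glucocorticoids, 15 had positive log2 fold changes (median 0.46); 2 passed, Cdkn1a and Sult1a1 (log2 0.74 ± 0.19; lost in 5 of 24 fits that left out 1 library and in 5 of 14 other settings), while Fkbp5 stood at 17.9 ± 9.68 CPM in cKO and 10.4 ± 1.77 in the Cre control (adjusted p = 0.120). The list passed camera (adjusted p = 0.00101), but the adjusted p was 0.480 with an estimated correlation. Of 12 cell cycle genes, 2 passed, among them Mcm5 (log2 -0.43 ± 0.11; lost in 3 of 24 such fits and in 4 of 14 settings), which takes part in DNA replication (median -0.27; camera adjusted p = 0.0340; adjusted p = 0.401 with an estimated correlation). All 10 tested blood genes had negative values (median -0.39, 0 called; camera adjusted p = 0.0209; adjusted p = 0.487 with an estimated correlation). Among 15 clock genes Cry1 passed (log2 0.37 ± 0.11), a call lost in 19 of 24 fits that left out 1 library and in 8 of 14 other settings (list median 0.14; camera adjusted p = 0.0367; adjusted p = 0.487 with an estimated correlation). Gabra2, a subunit of GABA receptors, stood at 54.9 ± 16.7 CPM in the Cre control, 26.3 ± 10.9 in the NDI1 control, 30.9 ± 8.44 in cKO and 16.5 ± 4.04 in cKO+NDI1, and passed in cKO against Cre control (log2 -0.83 ± 0.24, adjusted p = 0.0440), a call lost in 15 of 24 fits that left out 1 library and in 7 of 14 other settings. Its level in the NDI1 control was 12.6 to 21.5 CPM in males and 31.6 to 40.1 in females. Wdfy1 also split within groups, at 12.8 to 13.2 CPM in males and 41.7 to 46.4 in females of the NDI1 control. In cKO, Wdfy1 stood at 75.6 CPM in F1 and at 15.1 to 19.3 in the other libraries. What separated these libraries was not tested, so a difference among the mice other than the knockout is not excluded for Gabra2.

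In cKO+NDI1 against Cre control, 2 of 18 genes of disease-associated microglia passed: Cst7 (log2 2.99 ± 0.64) and Clec7a (1.45 ± 0.30), both at low counts and lost in 5 and 4 of 24 fits that left out 1 library (camera adjusted p = 0.0355; adjusted p = 0.478 with an estimated correlation). In cKO+NDI1, Cst7 stood at 1.60, 1.85 and 1.37 CPM in males and 0.216, 0.0655 and 0 in females, and Clec7a at 3.64, 3.89 and 4.12 in males and 2.16, 1.83 and 0.661 in females. In male against female mice, all 37 nuclear subunits of complex I had positive values (median 0.19, 0 called; camera adjusted p = 5.0e-07; adjusted p = 0.901 with an estimated correlation), and so did 17 of 20 homeostatic microglia genes (median 0.20; 0 called over all genes tested, 10 adjusted over the list alone; adjusted p = 7.3e-05, and 0.901 with an estimated correlation). The complex I list turned its direction with the surrogate variable, which correlates with the first principal component. Males and females of the control groups mostly lay apart on that component. A difference by sex in the complex I list therefore cannot be told apart from that structure of the samples.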
